A study of Homo sapiens with 4 samples.

How the data were processed

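RNA of MCF-7 cells was sequenced at days 0, 7, 14 and 21 of a HOMEZ Tet-on time course, with 1 library per day. The titles name the Tet-on system for every library, while the genotype given for day 0 is wild type, so whether the day 0 cells carried the construct is not settled. Per the labels' protocols, RNA was isolated with an RNeasy kit and 3 ug of total RNA entered each library, made with an NEBNext Ultra RNA kit for Illumina. No protocol states that the libraries keep the strand, so reads from overlapping genes on opposite strands cannot be told apart. The deposited values are FPKM, 1 value per Ensembl gene ID and library; the unit was read from the values, since the file headers name only the gene ID and the day. Their sums were 779803, 775353, 774370 and 782298 for days 0, 7, 14 and 21. Human builds hg19 and GRCh37 are named in the submitters' processing notes, where the mouse builds mm10 and GRCm38 stand as well. The aligner, the counter and the annotation are not given in the sources used here. No coordinates are given, because the annotation used for gene names is of another human build.

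Gene names and classes came from GENCODE 29, matched by Ensembl ID, which named 52338 of 57773 IDs (90.6%). Of the 5435 IDs without a name, 582 reached 1 FPKM in at least 1 library. These enter the counts over all gene classes and no named result. Of 683 distinct gene list symbols, 8 matched no ID (CD24, UHRF1, ACACA, PECAM1 and 4 histone genes).

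The deposited FPKM values proved to be whole multiples of a step for each gene, as values made from whole reads are. Genes with the same number of reads in a pair of libraries share 1 ratio, which gave the depth relative to day 0 as 0.9954, 0.9744 and 0.8981 for days 7, 14 and 21. Read numbers were then recovered for 31782 of 34110 genes above 0 (93.2%) and for 98.6% of the 15723 genes with at least 1 FPKM in any library. The implied length of 11684 genes equalled their merged exon length in GENCODE 29 to within 0.01 base, and these lengths gave the library totals, which stand for reads or fragments. Most genes with recovered reads had another implied length or no GENCODE 29 length. Genes with a value in 1 library were given the GENCODE 29 length where it made their reads whole, so their match was fixed in advance. Recovered reads made up 73.9% to 74.9% of the totals. Genes without recovered reads have no interval. Recovered reads served for counting intervals, depth, 1 alternative filter and data sets simulated with counting noise, and for no ratio or gene list. An exact 95% interval was computed for the ratio of 2 libraries (Clopper-Pearson, on the share of reads in the later library) and for single levels (Poisson). A count of 0 allows up to 3 reads, which in FPKM depends on the length of the gene. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

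Log2 ratios were differences of log2(FPKM + 1), without rescaling between libraries. A gene entered a comparison with at least 1 FPKM in 1 of the 2 libraries and counted as higher or lower from 2-fold. The printed ratios of named genes are ratios of the FPKM values without the pseudocount. With 1 library per day there was no test, no p-value and no error between samples. The plan written before the data were examined held 1 branch for counts and 1 for normalized values, and the second applied. The comparisons were days 7, 14 and 21 with day 0, day 14 with day 7 and day 21 with day 14. Overlaps of the 3 comparisons with day 0 were set beside 100 simulated data sets with no difference between days, whose spread was taken from the differences among the libraries of days 7, 14 and 21 by expression level. That spread contains any true difference between those days.

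Before the data were examined, 30 gene lists were fixed from general knowledge. They were estrogen receptor targets, luminal identity, basal and myoepithelial, epithelial junction, mesenchymal, stem cell, mitotic, DNA replication, p53, interferon, NF-kB and cytokine, ATF4 and integrated stress response, unfolded protein response, mitochondrially encoded, nuclear oxidative phosphorylation, hypoxia and glycolysis, cholesterol, fatty acid, TGF-beta, WNT, NOTCH, receptor tyrosine kinase, immediate early, drug efflux, HOX, HOMEZ-related, ribosomal protein, histone, leukocyte and fibroblast or endothelial genes. For each list the median log2 ratio of members above the floor was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries only, and lists with fewer than 5 measured members have none. Some genes belong to more than 1 list.

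The rule for named genes was fixed at the same time. It takes HOMEZ, the 12 protein-coding genes with the highest and the 12 with the lowest mean log2 ratio among those past 2-fold on all 3 later days, and the 5 highest and 5 lowest of each comparison with day 0. It also takes the 4 highest and 4 lowest of the other comparisons, among genes reaching 5 FPKM, and 2 to 4 members of each list with the largest absolute mean log2 ratio. Genes with near-identical copies are named as uncertain.

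Alternatives fixed beforehand were median-of-ratios scaling, a pseudocount of 0.1, no floor and a floor of 5 FPKM, thresholds of 1.5-fold and 4-fold, protein-coding genes only, leaving out 1 later day, and list members shared between lists left out. A filter of at least 50 recovered reads was chosen after seeing the data. On data drawn with counting noise from the mean read numbers of the 4 libraries, read recovery gave a value for 29286 of 29289 genes and all 4 read numbers right for 97.0% of those recovered. Each simulated gene was given its GENCODE 29 exon length, which 11684 genes had in the deposited values. The share of right read numbers was therefore not checked for genes with another length. In the simulated comparison of day 7 with day 0, 100% of 100 genes raised 4-fold and 99.0% of 100 genes lowered 4-fold were past 2-fold, as were 0.21% of 12156 unchanged genes. For the simulated lists of day 14 against day 0, 4.0% of 200 random lists lay outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.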

Results

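The messenger RNA of MCF-7 cells was sequenced on 4 days of a time course of induced HOMEZ expression. MCF-7 is an established, estrogen receptor positive human breast cancer line with luminal epithelial features, and HOMEZ encodes a homeobox protein with leucine zipper motifs. The titles of all 4 libraries name a HOMEZ Tet-on system, in which tetracycline switches on an introduced gene. The labels give the day 0 library the wild-type genotype and call the libraries of days 7, 14 and 21 HOMEZ overexpression, and they name tetracycline for all 4 libraries. The labels do not settle whether the day 0 cells carried the construct or were uninduced, so a comparison with day 0 may contrast genotype or drug treatment rather than induction alone. There was 1 library per day. The values are therefore those of single libraries, no difference below has a replicate check, and no p-value is given. Levels are in FPKM (fragments per kilobase of gene, scaled to the depth of the library), and the library totals behind them were 46835553 at day 0, 46617915 at day 7, 45635061 at day 14 and 42062834 at day 21. A level above 0 was listed for 28985, 27401, 27045 and 26084 genes in that order, and 1 FPKM or more for 14527, 14200, 14271 and 14140 genes. Ratios of named genes carry 95% counting intervals in brackets, which cover counting error only and compare libraries, not conditions.

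HOMEZ (ENSG00000215271, chromosome 14) was lowest in the day 0 library and higher in each later library. Its level was 22.8 FPKM at day 0 (95% counting interval 21.7 to 23.9, 1629 reads), 57.4 FPKM at day 7 (55.6 to 59.2, 4091 reads), 62.2 FPKM at day 14 (60.3 to 64.0, 4337 reads) and 41.8 FPKM at day 21 (40.2 to 43.4, 2689 reads). The ratio to day 0 was 2.52 (2.38 to 2.67) at day 7, 2.73 (2.58 to 2.89) at day 14 and 1.84 (1.73 to 1.96) at day 21. The day 21 library held 0.673 of the day 14 level (0.641 to 0.706). These values cannot separate reads of an introduced copy from reads of the cells' own gene. The HOMEZ levels go the way the labels say, with the day 21 library under the 2-fold threshold used below. Among the 8 measured members of the list of HOMEZ and related zinc finger homeobox genes, HOMEZ alone was at least 2-fold higher than day 0, at days 7 and 14. The median log2 ratios of that list were -0.12, -0.04 and 0.03 at days 7, 14 and 21, and its means were 0.01, 0.12 and 0.12. ZHX2, a related zinc finger homeobox gene, was at 20.9, 16.4, 18.7 and 19.6 FPKM on the 4 days.

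**Figure D1:**
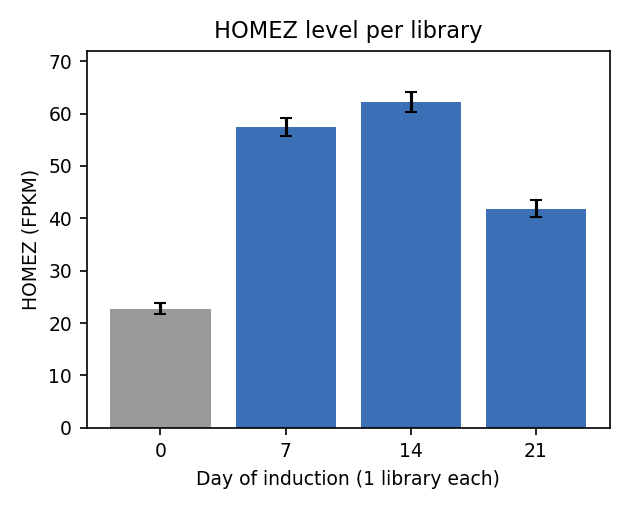
HOMEZ level in FPKM (vertical axis, from 0) in the library of each day (horizontal axis, 1 library per day), with day 0 in grey. Bars are the library's value and whiskers its 95% counting interval; the bars stand at 22.8, 57.4, 62.2 and 41.8 FPKM.

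The comparison of day 7 with day 0 asks how the transcriptome differed between the wild-type library and the first library labelled HOMEZ overexpression. Genes of the immediate early response and of cholesterol synthesis were higher at day 7, and genes of the mitotic cell cycle were lower. FOSB, a subunit of the AP-1 transcription factor, was at 5.90 FPKM at day 0 and 202 FPKM at day 7, a ratio of 34.2 (31.8 to 36.9). CTGF, a secreted matricellular protein, was at 0.593 and 40.0 FPKM (ratio 67.5, 52.8 to 87.6), and GSDMA, a member of the pore-forming gasdermin family, at 0.283 and 28.4 FPKM (ratio 100.4, 63.3 to 170). ATF3, a stress-responsive transcription factor, had a ratio of 28.0 (20.4 to 39.6), and RASD1, a small GTPase inducible by glucocorticoids, one of 12.1 (11.3 to 13.1). At the lower end, S100A8 and S100A9, the subunits of calprotectin, were at 106.6 and 193 FPKM at day 0 and at 3.41 and 21.8 FPKM at day 7. KIF12, a kinesin, was at 54.6 and 4.45 FPKM, and S100A7 (psoriasin) at 33.2 and 2.79 FPKM. SERF1B was at 15.0 and 0.782 FPKM, but this gene has a near-identical copy, so its value is uncertain. Of 15120 genes with at least 1 FPKM in 1 of the 2 libraries, 311 were at least 2-fold higher and 295 at least 2-fold lower at day 7, on the log2(FPKM + 1) scale, which understates the ratios of genes with low levels. Protein-coding genes made up 169 of the higher and 120 of the lower genes. The balance depended on the setting, with 371 higher and 248 lower under median-of-ratios scaling, 775 and 1163 at 1.5-fold and 531 and 731 with a pseudocount of 0.1. The median log2 ratio of all these genes was -0.10, so the day 7 library as a whole lay slightly below day 0, and scaling by the median of ratios moved that median to 0.

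The immediate early genes, which encode transcription factors and feedback regulators that respond to growth factors and stress within minutes, stood highest of the lists at days 7 and 14. At least 2-fold higher levels than at day 0 were found for 13 of 20 measured members at day 7, for 12 of 20 at day 14 and for 0 of 18 at day 21, and no member was 2-fold lower on any of these days. The median log2 ratio was 2.01 at day 7, 1.61 at day 14 and -0.10 at day 21, at percentiles 100, 100 and 3.6 of random lists of like expression. Without the members shared with other lists the medians were 1.36 at day 7 and 1.28 at day 14. DUSP1, a phosphatase that acts on MAP kinases, was at 10.9, 127 and 128 FPKM at days 0, 7 and 14 and at 13.6 FPKM at day 21. JUN, an AP-1 subunit, was at 33.2, 187, 187 and 38.7 FPKM. The list of cholesterol biosynthesis genes followed a similar course, with all 23 measured members above day 0 at days 7 and 14. At least 2-fold higher were 6 of them at day 7 and 9 at day 14, and 0 of 22 at day 21. The medians were 0.83, 0.92 and -0.02, at percentiles 100, 100 and 34.1. LDLR, the receptor for low-density lipoprotein, was at 28.5, 90.5, 101 and 25.2 FPKM on the 4 days. IDI1, which isomerises isopentenyl diphosphate, was at 37.0, 91.6, 110.5 and 41.8 FPKM, MSMO1, a sterol oxidase, at 21.1, 48.8, 73.2 and 25.6 FPKM, and STARD4, a sterol transport protein, at 0.740, 7.04, 7.53 and 0.672 FPKM. Fatty acid synthesis genes had medians of 0.45, 0.49 and 0.13 over 12 measured members (percentiles 100, 100 and 96.9), of which 1, 3 and 0 were at least 2-fold higher. SCD, the stearoyl-CoA desaturase, was at 34.5, 119, 115 and 37.5 FPKM, and ACSL3, an acyl-CoA synthetase, at 77.6, 139, 184 and 107.5 FPKM.

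Mitotic cell cycle genes were lower at days 7 and 14 and near the day 0 level at day 21. None of 32 members was above its day 0 level at day 7 or day 14. The differences were small, with medians of -0.63, -0.64 and -0.04 (percentiles 0.0, 0.0 and 25.1), and 1 member was past 2-fold, at day 7. This was AURKA, a mitotic kinase, at 113 FPKM at day 0 and 53.9, 65.0 and 100.6 FPKM later. PLK1, another mitotic kinase, was at 74.5, 43.0, 42.5 and 68.2 FPKM. DNA replication genes had medians of -0.25, -0.32 and 0.17 over 29 members (percentiles 0.1, 0.0 and 100), with 0 past 2-fold on any of the 3 days. MCM10, a replication initiation factor, was at 16.7, 8.84, 9.58 and 16.6 FPKM, and RRM1, the large subunit of ribonucleotide reductase, at 52.0, 35.8, 33.2 and 48.2 FPKM. The p53 target genes had medians of -0.14, 0.01 and 0.06 over 25 members, within the central 95% of random lists on each day, and 0 past 2-fold. PLK3, a stress-responsive kinase, was at 9.91, 17.1, 19.0 and 11.6 FPKM, and TP53INP1 at 15.9, 9.85, 11.6 and 9.39 FPKM. Replication-dependent histone genes had medians of 0.07, 0.59 and -0.06 over 11 members (percentiles 94.5, 100 and 33.4; mean at day 7 -0.01). The day 14 median was 0.13 without a floor. HIST2H2BE, at least 2-fold higher at day 14, was at 15.4, 27.9, 44.6 and 17.9 FPKM, and HIST1H2BC at 5.83, 11.7, 12.7 and 6.96 FPKM. The histone genes form families with similar copies, and their messages mostly lack a poly(A) tail.

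**Figure D2:**
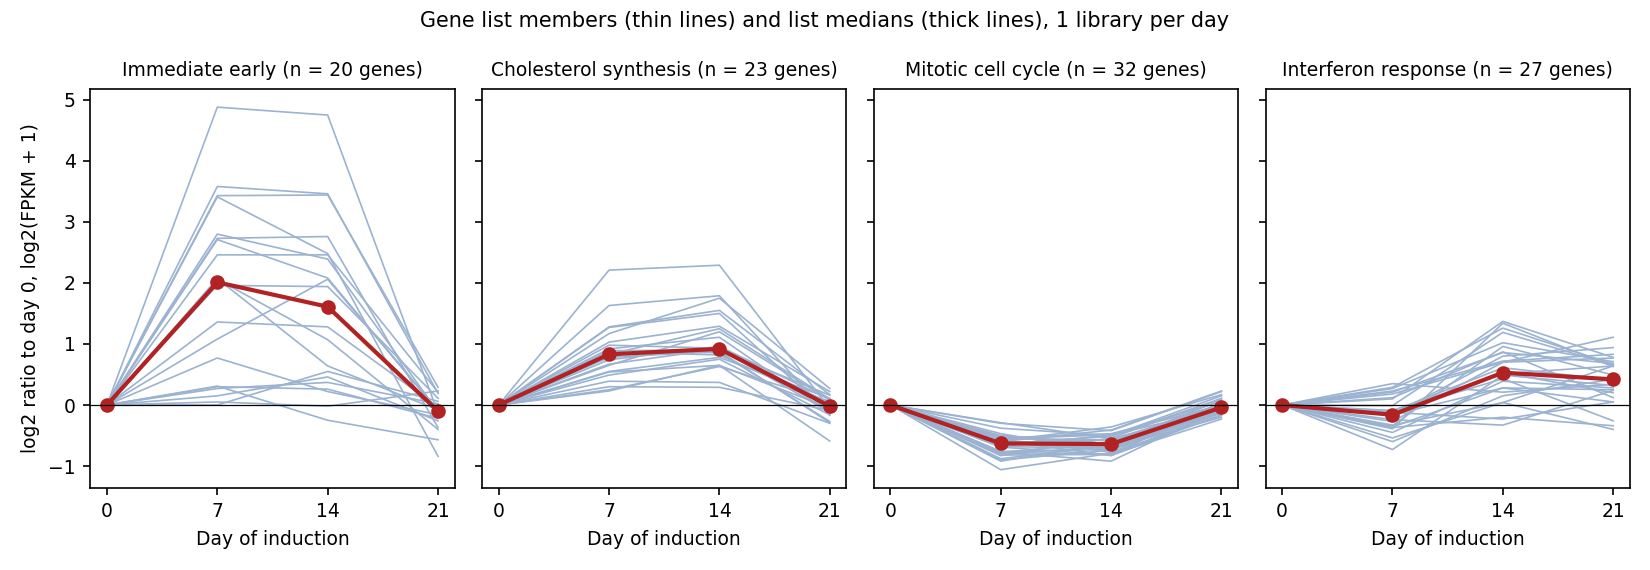
Log2 ratio to day 0 on the log2(FPKM + 1) scale (vertical axis) by day (horizontal axis) for the genes of 4 lists. Thin blue lines are single genes that reach 1 FPKM in any library and thick red lines are the medians of members reaching 1 FPKM in 1 of the 2 libraries compared, which for immediate early genes stand at 2.01, 1.61 and -0.10 and for cholesterol synthesis at 0.83, 0.92 and -0.02.

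At day 14 the same groups stood apart from day 0, and interferon response genes were higher as well. FOSB (ratio 31.3, 29.1 to 33.8), CTGF (84.5, 66.2 to 110), GSDMA (102.1, 64.4 to 173) and ATF3 (25.6, 18.6 to 36.3) were again among the 5 highest. TGFB2, a ligand of the TGF-beta family, was at 0.165 FPKM at day 0, 5.97 FPKM at day 7 and 24.1 FPKM at day 14, and its ratio to day 0 of 36.3 at day 7 (24 to 57.6) rests on 23 reads at day 0. The 5 lowest were S100A8 (1.63 FPKM at day 14), S100A7 (0.618 FPKM), S100A9 (11.2 FPKM), KIF12 (3.45 FPKM) and C3. The last of these, the central complement component, was at 20.1 FPKM at day 0 and 0.677 FPKM at day 14, a ratio of 0.0337 (0.0221 to 0.0494). Of 15192 genes, 409 were at least 2-fold higher and 392 at least 2-fold lower, of which 244 and 193 were protein coding. These numbers were 1028 and 1277 at 1.5-fold and 706 and 819 with a pseudocount of 0.1. Interferon response genes had a median of 0.53 at day 14 (percentile 100), with 24 of 27 measured members above day 0 and 5 of them at least 2-fold higher. At day 7 the median was -0.16 (percentile 13.2, 0 of 23 past 2-fold), or -0.33 with a floor of 5 FPKM, and at day 21 it was 0.42 (percentile 100, 1 of 24 past 2-fold). The measured members differed between days, since some passed the floor only through the later library. IFIT2 (0.490, 0.824 and 2.56 FPKM at days 0, 7 and 14) and RSAD2 (0.193, 0.441 and 1.42 FPKM) entered at day 14 but not at day 7. Both were among those at least 2-fold higher at day 14. IFIT1, an antiviral effector, was at 5.29, 5.72, 15.3 and 9.83 FPKM on the 4 days, and CMPK2, a mitochondrial nucleotide kinase, at 0.876, 1.12, 2.05 and 3.05 FPKM.

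By day 21 the immediate early and cholesterol synthesis genes were near the day 0 level, and hypoxia and glycolysis genes were lower than at day 0. GSDMA (13.8 FPKM, ratio 48.6, 30.5 to 82.4), TGFB2 (7.00 FPKM, ratio 42.5, 28.2 to 67.5), CEACAM6 (45.6 FPKM, ratio 7.91, 7.16 to 8.76), LAMB1 (59.0 FPKM, ratio 5.68, 5.26 to 6.14) and GALNT16 (10.6 FPKM, ratio 8.64, 6.94 to 10.9) were the 5 highest. CEACAM6 is a cell adhesion molecule of the carcinoembryonic antigen family, whose members are similar in sequence, LAMB1 is a laminin chain of basement membranes and GALNT16 an enzyme of O-glycosylation. Among the 5 lowest, MUC5B, a gel-forming mucin, was at 74.4 FPKM at day 0 and 14.1 FPKM at day 21 (ratio 0.190, 0.184 to 0.196), and LXN, a carboxypeptidase inhibitor, at 282 and 60.4 FPKM (ratio 0.214, 0.205 to 0.224). CA9, a hypoxia-inducible carbonic anhydrase, was at 5.67 and 0.243 FPKM (ratio 0.0428, 0.0193 to 0.0827). S100A7 was at 6.24 FPKM, and C17orf64, at 5.89 FPKM at day 0, had a ratio of 0.0160 (0.00192 to 0.0590) at day 21, on 2 reads. Of 15074 genes, 204 were at least 2-fold higher and 285 at least 2-fold lower, of which 83 and 90 were protein coding. Hypoxia and glycolysis genes had a median of 0.40 at day 7 (25 of 27 members above day 0, 3 past 2-fold), -0.03 at day 14 (mean 0.02) and -0.53 at day 21 (3 of 27 above day 0, 5 at least 2-fold lower). The percentiles were 100, 48.1 and 0.0. Among its members, ADM, the vasodilator peptide adrenomedullin, was above day 0 throughout, at 8.22, 41.7, 33.6 and 14.2 FPKM, and ENO2, an enolase, was at 75.4, 72.3, 55.5 and 36.3 FPKM. The ATF4 and integrated stress response list had medians of 0.20, 0.11 and 0.55 (percentiles 100, 98.7 and 100), with 2, 1 and 4 members at least 2-fold higher. ASNS, the asparagine synthetase, was at 42.1, 58.8, 63.3 and 99.3 FPKM, and CHAC1, which degrades glutathione, at 2.66, 7.38, 6.24 and 9.25 FPKM.

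A set of genes differed from day 0 in 1 direction on all 3 later days. It held 46 protein-coding genes at least 2-fold higher and 47 at least 2-fold lower, and 57 and 106 genes of any class. With a floor of 5 FPKM the balance over all classes turned, to 47 higher and 36 lower. Among the 12 highest by mean log2 ratio, LAMB1 was at 10.4 FPKM at day 0 and 79.6, 105 and 59.0 FPKM later, COL5A2, a fibrillar collagen chain, at 1.10, 6.83, 12.7 and 8.59 FPKM, and NTN4, a netrin of basement membranes, at 11.7, 39.5, 48.1 and 51.9 FPKM. KLK5 and KLK6, secreted serine proteases of the kallikrein family, were at 0.796 and 5.06 FPKM at day 0 and at 12.6 and 33.0 FPKM at day 14. CCDC80, a secreted matrix protein, was at 0.734, 4.54, 14.0 and 2.82 FPKM, and NT5E, which produces adenosine outside the cell, at 1.26, 5.91, 15.6 and 5.17 FPKM. PSG9, a pregnancy-specific glycoprotein of a family with similar copies, was at 1.08, 4.62, 10.9 and 8.30 FPKM. GSDMA, TGFB2, CEACAM6 and GALNT16 made up the rest of the 12.

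Among the 12 lowest genes of that set, S100A8 and S100A9 were at 25.9 and 67.5 FPKM at day 21, ratios to day 0 of 0.243 (0.223 to 0.265) and 0.349 (0.330 to 0.369). DHRS2, a short-chain dehydrogenase, was at 161 FPKM at day 0 and 27.4, 16.2 and 51.6 FPKM later, and CSTA, a protease inhibitor of keratinocytes, at 16.6, 1.80, 1.42 and 4.36 FPKM. LCN2, a siderophore-binding lipocalin, was at 9.62 FPKM at day 0, 1.02 FPKM at day 7 and 4.28 FPKM at day 21. At day 14 it was at 0.02965 FPKM on 1 read, and its ratio to day 0 was 0.00308 (7.78e-05 to 0.0173). AKR1C2, a steroid-metabolising reductase with close paralogs, was at 8.80, 1.04, 0.676 and 1.56 FPKM, NXPH3 at 13.8, 1.66, 0.797 and 2.70 FPKM, and FGG, the fibrinogen gamma chain, at 5.23, 0.483, 0.0730 and 0.436 FPKM. KIF12, S100A7, SERF1B and LXN were the others. Because the 3 comparisons share the day 0 library, such overlaps lie above 0 with no effect at all. In 100 simulated data sets with no difference between days, a mean of 15.7 protein-coding genes was higher and 13.6 lower on all 3 days, with highest counts of 24 and 23. Over all gene classes these means were 31.8 and 39.6 and the highest counts 47 and 53. Independent lists of the same sizes would give 0.024 and 0.015 protein-coding genes. The simulated data sets share a day 0 library too, so their counts already include the effect of sharing. The excess over them may come from a day 0 library that differed more than the later libraries did among themselves. With 1 day 0 library this cannot be told apart from induction. Without the day 21 library, the count over all gene classes was 378 in place of 163, without day 7 it was 255 and without day 14 it was 196. Leaving out a day can only keep or raise this count. Of the protein-coding genes past 2-fold at both day 7 and day 14, which numbered 136 higher and 96 lower, 54 and 18 were within 1.5-fold of day 0 at day 21. The overlap of days 7 and 14 also rests on the shared day 0 library. With no difference between days the simulated mean was 17.7 protein-coding genes per direction, and independent lists would give 3.5 higher and 1.9 lower. Over all gene classes, where 185 were higher and 193 lower on both days, the simulated mean was 54.1 per direction.

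**Figure D3:**
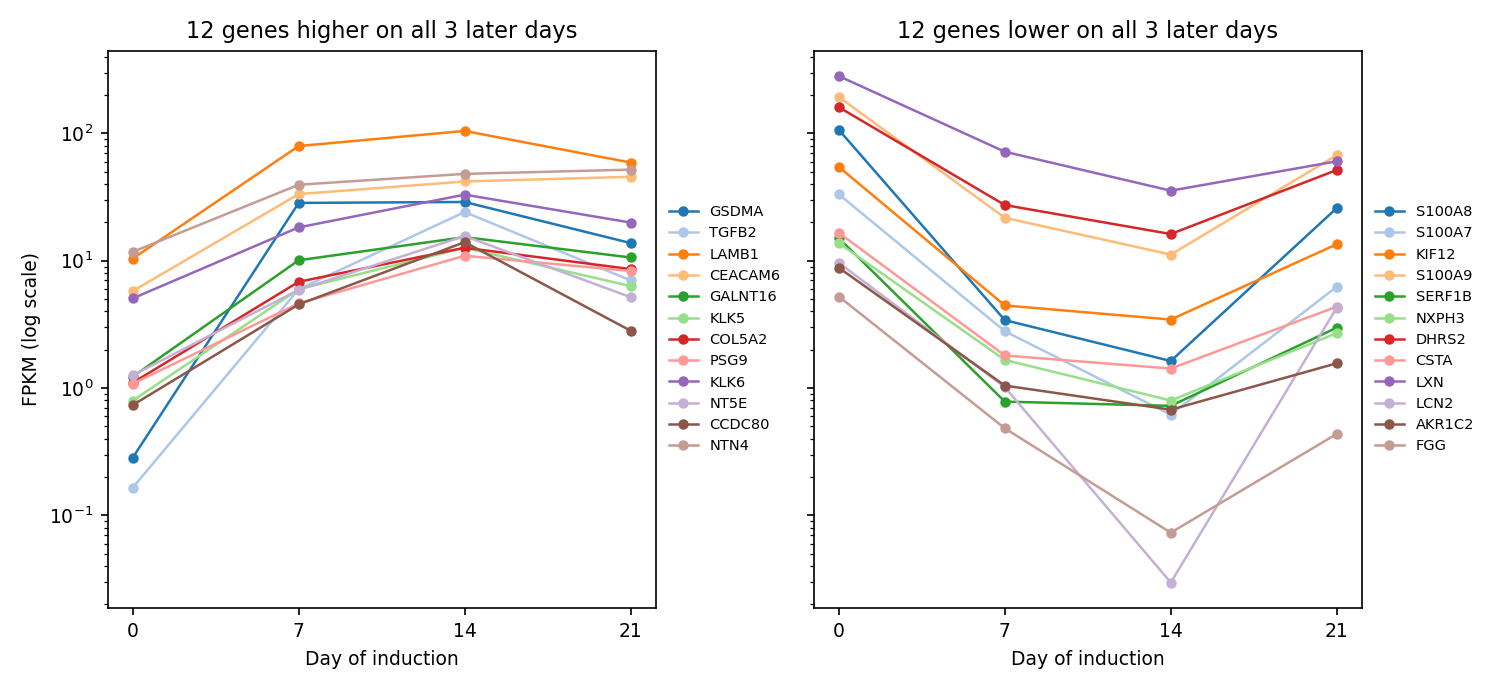
FPKM on a log scale (vertical axis) by day (horizontal axis, 1 library per day) of the 12 protein-coding genes with the highest and the 12 with the lowest mean log2 ratio among those at least 2-fold from day 0 on all 3 later days. LAMB1 goes from 10.4 FPKM at day 0 to 105 FPKM at day 14, and S100A8 from 106.6 to 1.63 FPKM.

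Between day 7 and day 14, the interferon response genes stood out. Their median log2 ratio of day 14 to day 7 was 0.68 (percentile 100), with 24 of 27 members higher at day 14 and 5 of them at least 2-fold. Histone genes had a median of 0.42 (percentile 100, 0 of 10 past 2-fold), and hypoxia and glycolysis genes one of -0.33 (percentile 0.0, 2 of 27 at least 2-fold lower). Basal and myoepithelial, cholesterol biosynthesis and p53 target genes also stood at percentile 100, with smaller medians of 0.30, 0.22 and 0.22. Receptor tyrosine kinase and growth factor genes had a median of -0.19 (percentile 0.0). IFI6, an interferon-inducible gene, was at 171 FPKM at day 7 and 567 FPKM at day 14 (ratio 3.32, 3.23 to 3.42). TGFB2 (ratio 4.04, 3.74 to 4.36) and KRT13, a keratin of stratified epithelia (5.13, 4.45 to 5.95), were also among the 4 highest, as was BOLA2B (8.75, 6.95 to 11.2), whose value is uncertain because it has a near-identical copy. The 4 lowest were FGB, the fibrinogen beta chain (5.67 and 0.636 FPKM), CNTD2, a cyclin-like gene (15.9 and 3.27 FPKM), CA9 (5.24 and 0.672 FPKM) and the chemokine CXCL17 (5.61 and 1.21 FPKM). In all, 154 of 14869 genes were at least 2-fold higher at day 14 and 136 at least 2-fold lower, of which 28 and 27 were protein coding. Median-of-ratios scaling turned this balance, to 143 higher and 159 lower.

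Between day 14 and day 21, immediate early, cholesterol synthesis and hypoxia genes were lower in the later library, and mitotic, DNA replication, and NF-kB and cytokine genes were on balance higher. The median log2 ratio of day 21 to day 14 was -1.65 for immediate early genes, with 12 of 20 at least 2-fold lower, and -1.08 for cholesterol biosynthesis genes, with 13 of 23 at least 2-fold lower. Hypoxia and glycolysis genes had a median of -0.56 (percentile 0.0), with 3 of 26 at least 2-fold lower. NF-kB and cytokine genes had a median of 0.75 (percentile 100), with 5 of 13 at least 2-fold higher and 1 lower. All 32 mitotic genes and all 29 DNA replication genes were above their day 14 level, with medians of 0.61 and 0.53 (percentile 100 for both), but 0 and 1 of them were at least 2-fold higher. FOSB was at 185 and 5.30 FPKM (ratio 0.0287, 0.0264 to 0.0311), CTGF at 50.1 and 1.61 FPKM, NR4A1, an orphan nuclear receptor, at 128 and 11.9 FPKM, and ATF3 at 17.5 and 0.917 FPKM. C3 was at 0.677 and 19.8 FPKM (ratio 29.2, 19.9 to 44.6), LTB, a cytokine of the tumour necrosis factor family, at 0.317 and 5.54 FPKM (ratio 17.5, 10.2 to 32.6), and S100A8 and S100A9 had ratios of 15.9 (11.7 to 22.2) and 6.04 (5.33 to 6.86). Of 14889 genes, 163 were at least 2-fold higher and 244 at least 2-fold lower at day 21, of which 32 and 86 were protein coding.

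Estrogen receptor target genes were on balance lower at days 7 and 14. Of 30 members, 5 were at least 2-fold lower at day 7, 9 at day 14 and 4 at day 21, and 2 were at least 2-fold higher on each day. The medians were -0.31, -0.26 and 0.10 (percentiles 0.0, 0.0 and 97.8). Without the members shared with other lists the medians were -0.41, -0.44 and -0.00, and the mean at day 21 was -0.04. PGR, the progesterone receptor, was at 18.9, 3.63, 2.02 and 5.61 FPKM, RERG, a small GTPase regulated by estrogen, at 29.9, 9.18, 6.08 and 13.8 FPKM, and RET, a receptor tyrosine kinase, at 69.1, 24.8, 18.1 and 40.6 FPKM. Luminal epithelial identity genes had medians of 0.14, 0.10 and -0.12 over 20 members (percentiles 99.6, 96.5 and 0.5; mean at day 14 -0.15), of which 1, 4 and 1 were at least 2-fold lower and 0 higher. The members farthest from day 0 were lower on all 3 days. MUC1, a membrane mucin, was at 35.2, 22.4, 11.3 and 12.9 FPKM, PRLR, the prolactin receptor, at 48.6, 23.1, 16.7 and 26.8 FPKM, and AR, the androgen receptor, at 12.3, 7.79, 5.50 and 5.74 FPKM. ESR1, which encodes the estrogen receptor itself and was chosen after its values were seen, was at 81.8, 45.5, 46.7 and 61.1 FPKM.

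Basal and myoepithelial genes were higher on balance, with medians of 0.34, 0.67 and 0.36 over 19 measured members (percentile 100 on each day) and 1, 6 and 3 at least 2-fold higher. CAV1, a component of caveolae, was at 3.69, 9.27, 23.9 and 9.72 FPKM, and LAMC2, a laminin chain, at 6.61, 12.7, 16.2 and 15.2 FPKM. Epithelial junction genes had medians of 0.19, 0.11 and 0.01 over 26 members (percentiles 100, 99.0 and 50.2), with 1, 2 and 1 at least 2-fold higher. CLDN1, a tight junction claudin, was at 2.41, 11.4, 16.6 and 7.24 FPKM, and CLDN4 at 149, 281, 306 and 186 FPKM. The 12 measured mesenchymal genes of 30 went both ways, with medians of -0.08, -0.12 and -0.12 inside the central range of random lists and means of 0.17, 0.05 and -0.09. Without shared members the day 14 median was 0.18. COL5A1, a collagen chain, was at 49.8, 158, 285 and 115 FPKM, and CD44, a hyaluronan receptor, at 27.5, 8.31, 8.49 and 14.3 FPKM. Stem cell and pluripotency genes had medians of 0.32, 0.59 and 0.33 over 12 measured members of 24, at percentile 100 on each day, with 2, 3 and 2 at least 2-fold higher and 1, 2 and 0 lower. The direction depended on the expression floor, since the medians were -0.01, -0.03 and -0.01 without a floor and the day 7 median was -0.02 with a floor of 5 FPKM. The day 14 median was 0.27 with that floor, and without shared members the medians were 0.03 at day 14 and 0.09 at day 21. MYC, a transcription factor that is also in other lists, was at 69.3, 211, 167 and 98.3 FPKM, ALDH1A3, a retinaldehyde dehydrogenase, at 1.06, 3.17, 2.89 and 4.61 FPKM, and KLF4 at 23.4, 44.2, 67.9 and 34.0 FPKM. The stem cell list also holds CD44, its member with the largest absolute mean log2 ratio (-1.37), which was lower on each later day.

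TGF-beta target genes had medians of 0.40, 0.65 and 0.12 over 18 measured members (percentiles 100, 100 and 97.6), with 5, 4 and 1 at least 2-fold higher and 1, 1 and 0 lower. CTGF, TGFB2 and CYR61, a matricellular protein at 7.81, 82.2, 95.5 and 11.6 FPKM, led the list, and ID2, an inhibitor of helix-loop-helix factors, was lower at 12.03, 3.83, 2.36 and 5.66 FPKM. CTGF and CYR61 also respond to growth factors and to mechanical signals. NF-kB and cytokine genes had medians of -0.37, -0.74 and 0.04 over 13, 12 and 13 measured members of 24 (percentiles 0.4, 0.0 and 85.0), of which 2, 5 and 0 were at least 2-fold lower and 1, 1 and 0 higher. The day 14 median was -0.38 without a floor. LTB was at 6.68, 0.620, 0.317 and 5.54 FPKM, ICAM1, an adhesion molecule, at 11.8, 4.73, 4.13 and 9.74 FPKM, and LIF, a cytokine of the interleukin-6 family, was higher at 12.9, 42.3, 39.8 and 16.9 FPKM. WNT target genes had medians of 0.07, -0.35 and -0.16 over 10 measured members (percentiles 90.1, 1.7 and 15.1), with MYC alone past 2-fold, at days 7 and 14. The day 14 median was 0.20 with a floor of 5 FPKM, and the day 7 median was -0.24 without shared members. NOTUM, which inactivates WNT proteins, was at 1.10, 0.420, 0.481 and 0.335 FPKM. NOTCH pathway genes had medians of 0.20, 0.02 and -0.01 (percentiles 99.7, 75.4 and 55.0; mean at day 21 0.08), with 2, 2 and 0 at least 2-fold higher. These were HES1, a transcriptional repressor, at 43.6, 105.5, 123 and 57.7 FPKM, and LFNG, a glycosyltransferase that modifies NOTCH, at 14.6, 36.0, 30.6 and 27.4 FPKM. Receptor tyrosine kinase and growth factor genes had medians of 0.09, -0.00 and -0.03 over 20 members (percentiles 99.3, 69.8 and 42.7), with 4, 3 and 1 at least 2-fold higher and 3, 3 and 1 lower. The day 7 median was -0.02 without a floor. FGFR4, a fibroblast growth factor receptor, was at 58.7, 28.7, 20.3 and 26.0 FPKM, IGFBP5, which binds insulin-like growth factors, at 182.5, 60.4, 66.4 and 94.4 FPKM, and AREG, a ligand of the epidermal growth factor receptor, at 23.5, 57.9, 50.8 and 49.3 FPKM.

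**Figure D4:**
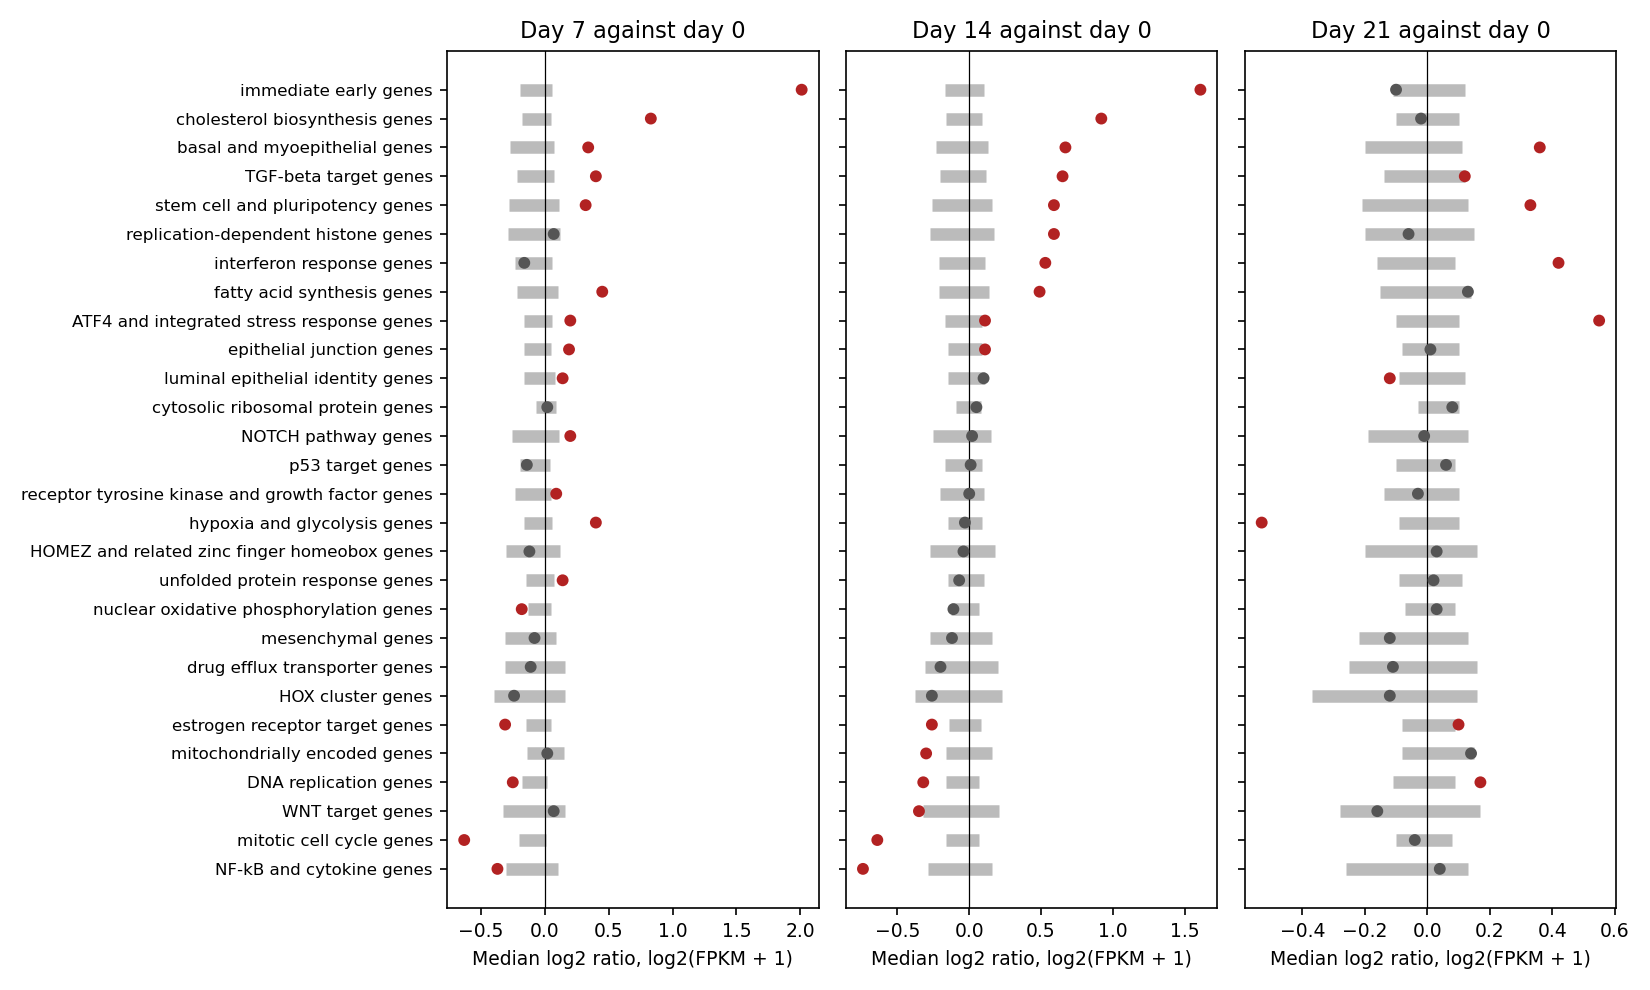
Median log2 ratio to day 0 (horizontal axes, log2(FPKM + 1) scale, a different range in each panel) of the 28 gene lists with at least 5 measured members, at days 7, 14 and 21. Grey bars are the central 95% of 10000 random lists matched on expression and red dots lie outside them; the immediate early list is farthest right at days 7 (2.01) and 14 (1.61), and the hypoxia and glycolysis list is farthest left at day 21 (-0.53).

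Unfolded protein response genes had medians of 0.14, -0.07 and 0.02 over 20 members (percentiles 99.8, 26.5 and 51.8; mean at day 21 -0.03), and 0 were past 2-fold. XBP1, a transcription factor of that response, was at 1644, 1086, 879 and 1117 FPKM, and HSPA5, a chaperone of the endoplasmic reticulum, at 133, 186, 153 and 142 FPKM. Mitochondrially encoded genes had medians of 0.02, -0.30 and 0.14 over 13 members (percentiles 60.6, 0.0 and 96.6; mean at day 7 -0.01), with MT-CO1, a subunit of cytochrome oxidase, at 13638, 10288, 9843 and 10840 FPKM and MT-CYB, cytochrome b, at 2274, 3012, 3068 and 2907 FPKM. Nuclear oxidative phosphorylation genes had medians of -0.18, -0.11 and 0.03 over 34 members (percentiles 0.1, 6.2 and 69.5), and the day 7 median was -0.07 with median-of-ratios scaling. The 1 member past 2-fold, at days 7 and 14, was COX6C, a subunit of cytochrome oxidase, at 1695, 817, 584 and 976 FPKM. Cytosolic ribosomal protein genes had medians of 0.02, 0.05 and 0.08 over 39 members, within the central range, and 0.12 at day 7 with median-of-ratios scaling, with RPS3 at 4920, 5439, 5673 and 5508 FPKM and RPLP0 at 2429.9, 2701, 2749.6 and 2636 FPKM. Drug efflux transporter genes had medians of -0.11, -0.20 and -0.11 over 8 measured members, also within the range. ABCG1, a cholesterol exporter, was at 11.4, 2.44, 1.501 and 8.78 FPKM, and ABCG2, a multidrug transporter, at 3.90, 3.86, 8.21 and 11.05 FPKM. HOX cluster genes had medians of -0.24, -0.26 and -0.12 over 9, 9 and 10 measured members of 39, with HOXC11 at 4.17, 2.57, 2.07 and 2.14 FPKM and HOXC6 at 5.165, 3.295, 2.82 and 2.95 FPKM, and these medians lay within the central range. Of 18 leukocyte markers, 1 reached 1 FPKM, CD79A, at 1.30 FPKM at day 7. Of the fibroblast and endothelial markers, 3 of 15 matched genes did, namely COL1A1 at 17.1, 11.6, 11.98 and 10.9 FPKM, EMCN at 3.96, 3.24, 2.86 and 2.78 FPKM and CDH5 at 0.130, 1.78, 0.719 and 1.02 FPKM. Over the 28 lists with at least 5 measured members and the 3 days, 43 of 84 medians lay outside the central 95% of random lists, where 4.2 would by chance if lists were independent random draws.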

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

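The test of a response in 1 direction and the question of the culture's state were chosen after the result was seen. Several results stood on opposite sides of day 0 on different days, and the difference between days was not tested, since there was 1 library per day. Estrogen receptor target genes had medians of -0.31 at day 7, -0.26 at day 14 and 0.10 at day 21, which turned to -0.00 at day 21 without shared members. Luminal epithelial identity genes had medians of 0.14, 0.10 and -0.12. DNA replication genes had medians of -0.25, -0.32 and 0.17. BHLHE40, a transcriptional repressor of the circadian clock that is also inducible by hypoxia, had log2 ratios of 1.04, 0.16 and -1.70, at 66.9, 139, 74.8 and 19.9 FPKM on the 4 days.

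Hypoxia and glycolysis genes had medians of 0.40 at day 7, -0.03 at day 14 and -0.53 at day 21, and ALDOC, an aldolase in that list, had log2 ratios of 1.07, 0.23 and -1.39. A gene length bias between libraries is argued against, because among random lists matched on expression and exon length the farther of the day 7 and day 21 percentiles lay 0.00 from the nearer end of the scale. The lower quartile of the members was 0.20 at day 7 and the upper quartile -0.13 at day 21, but the list was picked for these opposite signs, so this decides nothing about a response in 1 direction to HOMEZ, which was above day 0 on both days. The state of the culture at harvest, such as its density or oxygen supply, may account for the pattern and cannot be told apart from the day, because there was 1 culture per day. A delayed or indirect effect of induction stays open and untested.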

How the results depend on the processing

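The filter on recovered reads was the only setting chosen after the data were seen. Counts of genes past 2-fold moved with most settings, by construction where the threshold, the pseudocount or the set of genes was altered. In the order day 7, 14 and 21 against day 0, day 14 against day 7 and day 21 against day 14, the counts were 606, 801, 489, 290 and 407. They were 1938, 2305, 1645, 1078 and 1492 at 1.5-fold, and 57, 82, 26, 13 and 31 at 4-fold. A floor of 5 FPKM gave 275, 402, 164, 72 and 134, protein-coding genes alone 289, 437, 173, 55 and 118, and at least 50 recovered reads 356, 533, 236, 84 and 173. With a pseudocount of 0.1 they were 1262, 1525, 1146, 774 and 973. Of the counts for day 21 against day 14, 40.0% were higher at day 21 in the main setting and 24.6% with the floor of 5 FPKM. The count on all 3 later days was 163, and 581 at 1.5-fold, 10 at 4-fold, 83 with the floor of 5 FPKM, 93 in protein-coding genes and 435 with the pseudocount of 0.1. It was 378 without day 21, 255 without day 7 and 196 without day 14, where leaving out a day can only keep or raise it. Of the 24 named genes past 2-fold on all 3 days, 8 were past 4-fold. Leaving out the floor could not move these counts, since genes under 1 FPKM cannot reach 2-fold with a pseudocount of 1. Median-of-ratios scaling moved the HOMEZ log2 ratio at day 7 from 1.30 to 1.40 and the day 7 median of all genes from -0.10 to 0. It moved 81 of 84 list medians by less than the distance from the middle to the end of the random lists' central range, and the others at day 7 were ribosomal protein genes (0.12), estrogen targets (-0.21) and nuclear oxidative phosphorylation genes (-0.07). Among lists outside that range, the medians that reversed were WNT targets at day 14 with the floor of 5 FPKM (0.20), estrogen targets at day 21 without shared members (-0.00), receptor tyrosine kinase genes at day 7 without a floor (-0.02), and stem cell genes at day 7 with the floor of 5 FPKM (-0.02) and at days 7, 14 and 21 without a floor (-0.01, -0.03 and -0.01); the cause was not tested. No paired analysis was possible because there was 1 library per day and no test. Depth limits genes with few reads, such as TGFB2 with 23 and GSDMA with 18 reads at day 0, whose ratios have wide intervals. The low ratios of LCN2 and FGG at day 14 rest on 1 and 4 reads, and that of C17orf64 at day 21 on 2 reads.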

Other observations

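The tests of proportion to HOMEZ, the test of counting error and the questions of the culture's state and of the day 0 culture were chosen after the results were seen. Other genes, chosen after their values were seen, showed related courses. Of the keratins, KRT80 was at 44.8, 127, 160 and 103 FPKM on days 0, 7, 14 and 21, KRT81 at 483, 1383, 1237 and 1016 FPKM and KRT86 at 11.8, 36.3, 44.1 and 30 FPKM. KRT81 and KRT86 are hair keratins of closely similar sequence, so the values of both are uncertain. PSG5, a relative of PSG9, was at 0.362, 2.62, 6.27 and 2.71 FPKM. FGB and FGG, 2 chains of fibrinogen, were at 14.2 and 5.23 FPKM at day 0 and at 0.636 and 0.0730 FPKM at day 14. ABCG1, a cholesterol exporter, was lower on the days when cholesterol synthesis genes were higher, with log2 ratios of -1.86, -2.31 and -0.35. MYLIP, which marks the LDL receptor for degradation, had log2 ratios of -0.32, -0.37 and 0.12.

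Immediate early and cholesterol synthesis genes were higher at days 7 and 14 than at days 0 and 21. A gene length bias is argued against, since the lowest of the 4 percentiles among random lists matched on expression and exon length was 100. A response in proportion to the HOMEZ level, which at day 21 was 0.60 of its day 14 log2 ratio, predicts day 21 medians of 0.97 and 0.56. The observed medians were -0.10 (quartiles -0.25 to 0.05) for immediate early genes and -0.02 (quartiles -0.15 to 0.10) for cholesterol synthesis genes, both below the prediction. But the lists were picked for standing higher at days 7 and 14 than at day 21, so this decides nothing about proportion. The state of the culture at harvest, such as fresh medium, serum or density, may account for the pattern and cannot be told apart from the day with 1 culture per day, and a HOMEZ response with a threshold stays open and untested.

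The 93 protein-coding genes at least 2-fold from day 0 on all 3 later days are not explained by counting error of independent reads. Added spread from duplicate reads was not covered. In 100 data sets drawn with counting noise alone from the reads pooled over the 4 libraries, the highest number of such genes was 0. Over all gene classes it was 8, with a mean of 2.57, against 154 observed among genes with recovered reads. A day 0 culture that differed for other reasons than induction, such as genotype or drug treatment, may account for them, and with 1 day 0 culture this cannot be told apart from HOMEZ.

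The hypothesis that targets of YAP and TEAD were higher together came from CTGF, CYR61, TGFB2, NT5E, CCDC80, AMOTL2 and CRIM1, known targets of these transcriptional regulators, all of which were seen to be higher. At day 21, CTGF and CYR61 were under 2-fold on the log2(FPKM + 1) scale, with log2 ratios of 0.71 and 0.51. The hypothesis was tested on 15 other targets written down before their values were looked at, of which 10 were measured and 3 also belong to fixed lists whose medians had been computed. The others stayed under 1 FPKM. Of these, ANKRD1 was higher on each later day, AXL, FOXF2 and RBMS3 were lower on each, and F3 went both ways. The median log2 ratios of the 10 measured targets were 0.31, 0.78 and 0.31 at days 7, 14 and 21. The lowest of the 3 percentiles among random lists was 100, as the hypothesis predicted. Basal and myoepithelial genes and stem cell genes also stood at percentile 100 on each day, so such a percentile is not particular to these targets. Above day 0 were 9, 9 and 7 of the 10, and at least 2-fold higher 2, 2 and 0. Among them, DOCK5 was at 17.8, 44.6, 43.7 and 28.96 FPKM and MYOF at 93.4, 115, 168 and 171 FPKM. Below day 0 were GADD45A at day 7 (log2 ratio -0.26), ARHGEF17 at days 14 (-0.03) and 21 (-0.17), and NUAK2 (-0.07) and IGFBP3 (-0.01) at day 21. YAP and TEAD activity also depends on cell density, so this does not separate induction from the state of the culture.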
